A study of Solanum lycopersicum with 6 samples.

How the data were processed

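RNA was sequenced from the aerial part of tomato seedlings of 3 genotypes, Zhongshu 4 (ZS4) and the 35S:SlMYB14 lines OE5 and OE7, with 2 libraries each. Per the labels, each library came from a separate pool of 10 seedlings, poly(A) RNA was selected with oligo(dT) beads, and cDNA was made with random hexamers. Groups and replicate numbers were taken from the sample titles. The aligner, the quantification tool and the genome build are not given in the sources used here. Values named here FPKM, which scale fragments by gene length and library size, were deposited per gene and library to 2 decimals, per the file headers. Gene lengths in bases were deposited as well. Per the file headers, the authors also deposited 1 table per line with a mean expression signal per genotype, a log2 fold change of the line over ZS4, and a p-value with its adjusted p-value. Those comparison values were used only as the authors' own. The deposited gene descriptions served to name genes and to build gene lists, and 17051 of the 23571 genes (72.3%) matched the reference gene table by protein accession. The chromosome and order that the gene identifiers carry were used only to ask which genes lie near each other. They gave the chromosome of the reference gene table (assembly SLM_r2.1) for 99.9% of 13132 matched genes, with a Spearman correlation of order and position of at least 0.981 on each chromosome. No coordinates are given, since no genome was used here.

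The comparisons were fixed before the data were examined and assumed counts, with edgeR as the test. The files held FPKM, so limma with an intensity trend on log2(FPKM + 1) replaced it, as the same plan provided. All 6 libraries entered 1 fit with genotype as the factor, and the contrasts were OE5 minus ZS4, OE7 minus ZS4, OE7 minus OE5 and the mean of both lines minus ZS4. Genes with a mean of at least 1 FPKM were tested (16602), and calls were made at a Benjamini-Hochberg adjusted p below 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and fold values without log2 are ratios of mean FPKM. With 2 pools per genotype, p-values rest on a spread shared by all 3 genotypes, whose root mean square SD (log2) was 0.245 in ZS4, 0.482 in OE5 and 0.249 in OE7. They measure the spread between pools of a genotype, not between independently transformed lines, also for the mean of both lines. ZS4 was untransformed, so effects of transformation itself cannot be told apart from those of SlMYB14. An FPKM of 0 is reported as listed at 0.

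For 25 gene lists fixed beforehand from descriptions and identifiers, camera was run with a preset correlation of 0.01 on the same values, with Benjamini-Hochberg adjustment over the lists within each comparison, and again with an estimated correlation and with fry. Pathway enrichment used a one-sided Fisher's exact test over 126 pathways of 5 to 1000 genes, with the 6505 tested genes that carry a pathway annotation as the background, and was chosen after seeing the data. Named genes followed a rule fixed beforehand. It takes the 12 risen and 12 fallen genes with the largest change in both lines and an informative description, the 6 largest per direction called in 1 line alone, up to 4 members of each list with the smallest larger adjusted p of both lines together with the members listed by identifier, and up to 5 genes per direction for OE7 against OE5.

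The deposited signal columns behave as group means of scaled gene counts, since low values lie on whole multiples of a step per library. Reads per library were recovered from these means, the FPKM ratio of the replicates and the steps. At the best depth ratio, 87.1% to 90.9% of the searched low genes were whole within 0.1 read, against a median of 0.224% to 16.3% over other ratios. The ZS4 reads, recovered separately from both tables, were equal for 95.5% of 22059 genes and within 2 reads or 2% for 99.3%. The totals were 9112570 and 9112017 reads for ZS4, 9256483 and 9114981 for OE5, and 9010146 and 9451898 for OE7. On these reads edgeR's quasi-likelihood test (TMM or RLE factors, with and without a filter) and DESeq2 were run as alternatives chosen after seeing the data. They called 66 genes (edgeR, TMM) and 182 (DESeq2) in OE5, and 123 and 268 in OE7.

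The other alternatives were a pseudocount of 0.1, no filter on low values, an absolute log2 fold change of at least 1, the replicate number as a block, only the 4 libraries compared, FPKM scaled to equal medians, each library left out in turn, and, for the correlation of fold changes, separate ZS4 libraries. The block, added to the limma and edgeR fits, is reported with the other alternatives, since the replicate numbers name pools and the labels tie them to no shared batch. Without a library, its genotype has 1 pool, which is assumed to vary like the other groups.

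The fits, the list test and the read recovery were tested on simulated data, the fits with 200 changed genes among the real ones, 50 at each size. Of the 50 genes at log2 changes of 0.5, 1, 2 and 3, limma called 0, 17, 46 and 48 for OE5 and 0, 13, 46 and 48 for OE7, among 16602 genes. It also called 15 unchanged genes in either line, which is 11.9% and 12.3% of all calls, above the nominal 5%. A list of 13 genes shifted by 0.5 was recovered by camera for the mean of both lines (adjusted p = 1.80e-13) and 0 of the other lists passed. The simulated genes varied independently in a single draw, so this test could not show false list calls that come from correlated genes. In the data the estimated correlation was 0.342 for phenylpropanoid entry genes and 0.896 for ribosomal protein genes, against the preset 0.01. Simulated reads of the ZS4 libraries were recovered exactly for 98.7% of genes. Analyses used R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.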

Results

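The transcriptomes of tomato seedlings that overexpress SlMYB14 were compared with those of their background cultivar. SlMYB14 is an R2R3-MYB transcription factor gene, and 2 independent transgenic lines, OE5 and OE7, carried it behind the constitutive 35S promoter. Zhongshu 4 (ZS4), the untransformed cultivar, was the control. Polyadenylated RNA came from the aerial part of seedlings 1 week old, grown without stress at 28 °C under 150 μmol photons per square metre per second and 16 h of light a day. Each genotype had 2 replicates, each a separate pool of 10 seedlings, which makes 6 libraries. Per-gene FPKM values were listed for 23571 genes, of which 16602 had a mean of at least 1 FPKM over the libraries and were tested. Between 9010146 and 9451898 reads per library were assigned to genes, as recovered from the deposited values.

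Most libraries were closely alike, and OE5 replicate 2 stood apart from the other 5. Across genes, the Pearson correlation of log2(FPKM + 1) was 0.981 between the ZS4 replicates, 0.984 between the OE7 replicates and 0.953 between the OE5 replicates. OE5 replicate 1 correlated at 0.98 and 0.987 with the OE7 libraries, while OE5 replicate 2 correlated at 0.951 to 0.961 with all other libraries. The median over genes of its log2 deviation from the gene's mean over all libraries was 0.297, against −0.182 to 0.049 in the others. Its 10 most abundant genes took 19.98% of the summed FPKM, against 23.1% to 26.0% elsewhere. The median change of all tested genes against ZS4 was 0.04 in OE5 and −0.16 in OE7 on the log2 scale, and the camera tests of gene lists compare a list with all other genes, relative to that shift.

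**Figure D1:**
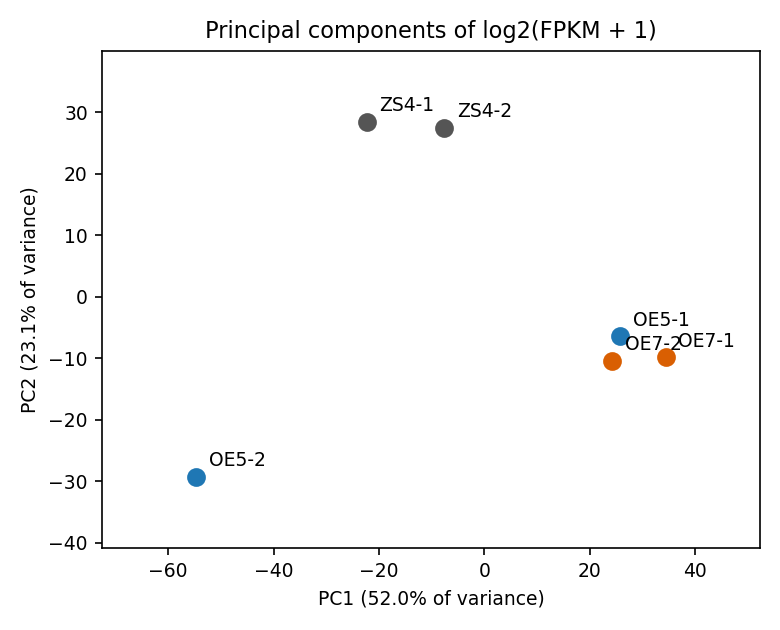
Principal components of log2(FPKM + 1) over the 16602 tested genes, with each point a library (grey ZS4, blue OE5, orange OE7), PC1 on the x axis (52.0% of the variance) and PC2 on the y axis (23.1%). OE5 replicate 2 sits at −54.7 on PC1, while OE5 replicate 1 lies beside the OE7 libraries.

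The first comparison asked whether a MYB gene was raised in both lines. One of the 67 tested MYB-family genes rose, a myb-related protein Myb4-like gene (Solyc06g083900.3). It had 0.690 ± 0.537 FPKM (SD, n = 2) in ZS4, 47.0 ± 6.34 in OE5 and 54.2 ± 12.3 in OE7 (SD, n = 2 each). These levels are 68.1-fold and 78.6-fold higher than in ZS4. Its limma log2 fold changes were 4.86 ± 0.28 (SE, adjusted p = 0.000632) in OE5 and 5.05 ± 0.28 (SE, adjusted p = 0.000578) in OE7. The ZS4 level rests on 7 and 2 reads, against 282 to 426 reads in each overexpression library. No gene description and no symbol in the gene table of the reference names MYB14, so none of the 110 listed MYB genes is identified here as the transgene, and the genotype labels could not be checked by it. Reads of a transgene and of the native gene cannot be told apart in such a table.

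In OE5, genes of the first steps of phenylpropanoid synthesis were higher than in ZS4. A phenylalanine ammonia-lyase-like gene (Solyc09g007900.4), of the enzyme family that opens the pathway, rose from 5.0 ± 1.15 FPKM (SD, n = 2) in ZS4 to 51.7 ± 0.552 (SD, n = 2), 10.3-fold. Its limma log2 fold change was 3.15 ± 0.20 (SE, adjusted p = 0.000859). The identifier of this gene lies close to that of the adenosine kinase 2-like gene Solyc09g007940.3, which was near 0 in every overexpression library. A chromosome segment that differs between ZS4 and the lines is therefore not excluded for it. The entry genes named next have identifiers of other chromosomes. A second phenylalanine ammonia-lyase gene (Solyc10g086180.2) rose from 106 ± 0.728 to 360 ± 11.3 FPKM (SD, n = 2 each). The trans-cinnamate 4-monooxygenase-like gene (Solyc06g150137.1), of the next step, rose from 95.05 ± 3.42 to 333 ± 2.92 FPKM. The gene of 4-coumarate--CoA ligase 1 (Solyc03g117870.3), which activates coumarate for the branch pathways, rose from 46.1 ± 0.170 to 156 ± 2.29 FPKM. That of 4-coumarate--CoA ligase 2 (Solyc06g068650.4; chosen after its values were seen) rose from 23.0 and 20.49 FPKM in the ZS4 libraries to 90.8 and 82.5. Of the 13 tested phenylpropanoid entry genes, 6 rose and 0 fell, or 9 and 0 adjusted over the list alone. Their median log2 fold change was 1.25 (camera adjusted p = 2.28e-20, adjusted p = 0.514 with an estimated correlation, fry adjusted p = 0.0367).

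Over all 16602 genes, 78 passed in OE5 at an adjusted p below 0.05, of which 36 rose and 42 fell. The flavonoid and anthocyanin enzyme list had 1 of 41 members risen, or 15 risen and 1 fallen adjusted over the list alone. Of the 41 genes 31 lay above the ZS4 mean (camera adjusted p = 8.36e-08, adjusted p = 0.689 with an estimated correlation). The ZS4 libraries themselves differed in this list, with replicate 2 above replicate 1 in 28 of the 41, and both OE5 libraries lay above both ZS4 libraries in 20 and below both in 5, against 2344 and 2199 of all 16602 genes, where chance gives 16.7% each way. The member that rose was a crocetin glucosyltransferase-like gene (Solyc12g098590.3), from 44.9 ± 19.4 to 144 ± 10.2 FPKM (SD, n = 2 each), a call lost in 14 of 16 alternatives (adjusted p up to 0.216). Dihydroflavonol-4-reductase (Solyc02g085020.4) stood at 28.6 ± 13.2 and 79.5 ± 1.67 FPKM and chalcone synthase 2 (Solyc05g053550.3) at 85.0 ± 39.2 and 215 ± 44.0 FPKM in ZS4 and OE5, with limma adjusted p = 0.101 and 0.165. Among genes that passed in OE5 and missed the threshold in OE7, a TRANSPARENT TESTA 12-like transporter gene (Solyc10g081260.2) rose from 16.2 ± 1.82 to 40.8 ± 7.28 FPKM and a 2-oxoglutarate-dependent dioxygenase gene (Solyc12g006380.2) fell from 39.5 ± 19.98 to 3.76 ± 0.283 FPKM. Their OE7 levels were 37.6 ± 2.31 and 7.57 ± 3.39 FPKM, and the call of the transporter gene was lost in 10 of 16 alternatives.

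The WRKY list was lower in OE5 than in ZS4 relative to all genes (camera adjusted p = 0.0249, adjusted p = 0.9855 with an estimated correlation), with 2 of 37 members fallen, or 3 adjusted over the list alone, although 18 members lay above ZS4 and 19 below (median log2 fold change −0.04). WRKY transcription factor 81 (Solyc09g015770.3) fell from 11.2 ± 0.771 to 0.660 ± 0.156 FPKM (SD, n = 2 each), and WRKY transcription factor 51 (Solyc04g051690.4) was listed at 8.57 and 4.75 FPKM in the ZS4 libraries and at 0 in both OE5 libraries, a call lost in 11 of 16 alternatives. Photosynthesis genes were lower (63 of 74, 0 past the test also when adjusted over the list alone, camera adjusted p = 1.24e-08, adjusted p = 0.975 with an estimated correlation). Cytosolic ribosomal protein genes were higher (179 of 200, 0 past the test also when adjusted over the list alone, camera adjusted p = 1.86e-04, adjusted p = 0.9855 with an estimated correlation). Both list directions turned without OE5 replicate 2, the library that stood apart, with camera adjusted p = 0.817 for photosynthesis and 1.09e-07 for the ribosomal genes. Heat shock genes were lower (34 of 62, 0 past the test also when adjusted over the list alone, camera adjusted p = 0.0249, adjusted p = 0.9855 with an estimated correlation). Leaving out 1 library ended 3 other list calls: flavonoid without OE5 replicate 1 (camera adjusted p = 0.740), WRKY without OE5 replicate 2 (0.460), and heat shock without OE5 replicate 1 (0.650) or ZS4 replicate 1 (0.0986). The 78 calls became 10 without ZS4 replicate 1, 302 without OE5 replicate 1 and 23 without either OE7 library, and 182 with DESeq2 on recovered reads. Risen and fallen genes numbered 31 and 23 with pseudocount 0.1, 12 and 37 with no filter on low values, 221 and 81 without OE5 replicate 1, and 95 and 87 with DESeq2.

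In OE7, the same steps of phenylpropanoid synthesis were higher than in ZS4. The phenylalanine ammonia-lyase-like gene Solyc09g007900.4 rose to 50.4 ± 5.47 FPKM (SD, n = 2), 10.1-fold. Its limma log2 fold change was 3.11 ± 0.20 (SE, adjusted p = 0.000902). Solyc10g086180.2 rose to 425 ± 81.9 FPKM, the trans-cinnamate 4-monooxygenase-like gene Solyc06g150137.1 to 350 ± 24.8 and the gene of 4-coumarate--CoA ligase 1 (Solyc03g117870.3) to 178 ± 28.7 (SD, n = 2 each). Of the 13 entry genes 7 rose and 0 fell, or 9 rose and 1 fell adjusted over the list alone. Their median log2 fold change was 1.36 (camera adjusted p = 4.04e-21, adjusted p = 0.444 with an estimated correlation, fry adjusted p = 0.0320). The added member was phenylalanine ammonia-lyase 3 (Solyc09g007920.4), from 142 ± 15.3 FPKM in ZS4 to 289 ± 25.6 in OE7, with 248 ± 2.47 in OE5 (SD, n = 2 each), a call lost in 11 of 16 alternatives.

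Over all tested genes, 105 passed in OE7, of which 37 rose and 68 fell; with FPKM scaled to equal medians, chosen after seeing the data, 54 rose and 54 fell. The flavonoid and anthocyanin list had 0 members past the limma test, where 1423 genes in OE7 had an unadjusted p below 0.05, or 8 risen adjusted over the list alone. Of the 41 genes 28 lay above the ZS4 mean (camera adjusted p = 1.01e-10, adjusted p = 0.444 with an estimated correlation). Both OE7 libraries lay above both ZS4 libraries in 20 of the 41 and below both in 4, against 2089 above and 7157 below among all 16602 genes, where chance gives 16.7% each way. The chalcone synthase 1 gene (Solyc09g091510.3) stood at 22.2 and 50.7 FPKM in ZS4 and at 44.9 and 46.8 in OE7 (limma adjusted p = 0.750). The gene of a salicylic acid carboxyl methyltransferase (Solyc09g091550.3), which makes methyl salicylate, fell from 19.6 ± 3.46 to 1.61 ± 0.24 FPKM (SD, n = 2 each), a 12.2-fold drop (limma log2 fold change −2.97 ± 0.23 SE, adjusted p = 0.00227). A peroxidase 3 precursor gene (Solyc05g046020.3) fell from 5.33 ± 1.11 to 0.135 ± 0.0636 FPKM, a premnaspirodiene oxygenase gene (Solyc08g005650.3) from 7.53 ± 0.530 to 0.730 ± 0.0566 FPKM, and catalase isozyme 1 (Solyc12g094620.3; chosen after its values were seen) by 1.51 on the log2 scale (limma adjusted p = 0.0252).

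The lists of pathogenesis-related, heat shock, class III peroxidase and cell cycle and histone genes were lower in OE7 relative to all genes. All tested genes also shifted down in OE7 (median log2 fold change −0.16), which the counts of lower members below include. Both OE7 libraries lay below both ZS4 libraries in 38 of 64, 37 of 62, 16 of 26 and 57 of 76 genes of these lists, against 7157 of all 16602. Of 64 pathogenesis-related genes 53 lay below ZS4 and 1 fell, or 3 adjusted over the list alone (camera adjusted p = 0.00103, adjusted p = 0.761 with an estimated correlation). The gene that fell, pathogenesis-related protein P2 precursor (Solyc01g097240.3), went from 4.39 ± 0.636 to 0.490 ± 0.0707 FPKM (SD, n = 2 each). Of 62 heat shock genes 50 were lower and a heat shock cognate 70 kDa protein gene (Solyc11g066100.2) fell from 11.98 ± 3.37 to 2.55 ± 0.24 FPKM, or 5 genes adjusted over the list alone (camera adjusted p = 0.00645, adjusted p = 0.866 with an estimated correlation). Of 26 class III peroxidase genes 23 were lower and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.0218, adjusted p = 0.761 with an estimated correlation). Of 76 cell cycle and histone genes 71 were lower and 1, the histone H3.2-like gene Solyc01g073970.3, fell, also when adjusted over the list alone (camera adjusted p = 0.00750, adjusted p = 0.909 with an estimated correlation). Other lists of hormone and stress genes did not pass in OE7. Camera adjusted p was 0.134 for WRKY and 0.621 for jasmonate genes, which tested toward lower. It was 0.132 for antioxidant enzymes, 0.434 for ABA and water deficit, 0.669 for glutathione transferases and 0.850 for ethylene. The latter lists tested toward higher only relative to all genes. In the same order, 23 of 41, 59 of 92, 20 of 31 and 51 of 71 of their members lay below ZS4.

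Photosynthesis genes lay higher than the other genes in OE7, although 40 were above ZS4 and 34 below (median log2 fold change 0.02; 0 of 74 past the test, or 1 risen adjusted over the list alone, camera adjusted p = 3.02e-05, adjusted p = 0.761 with an estimated correlation). Against all genes, 3 further lists tested as higher in OE7 although their median log2 fold changes were below 0. These were ribosomal proteins (median −0.01, camera adjusted p = 0.00657, adjusted p = 0.909 with an estimated correlation), MYB genes (median −0.06, camera adjusted p = 0.0390, adjusted p = 0.835 with an estimated correlation) and UDP-glycosyltransferases (median −0.02, camera adjusted p = 0.0287, adjusted p = 0.761 with an estimated correlation). Adjusted over the list alone, 0 ribosomal, 2 MYB and 2 UDP-glycosyltransferase genes rose and 1 UDP-glycosyltransferase gene fell. Without OE7 replicate 1 the ribosomal list turned direction (camera adjusted p = 0.752) and the photosynthesis (0.0671) and MYB (0.229) calls ended. Without OE7 replicate 2 the cell cycle (0.137) and UDP-glycosyltransferase (0.104) calls ended, as they did without ZS4 replicate 1 (0.191 and 0.0898). Without ZS4 replicate 2 the MYB (0.0751) and ribosomal (0.0504) calls ended, and equal medians ended the UDP-glycosyltransferase call (0.0532). The 105 calls became 10 without ZS4 replicate 1, 52 without ZS4 replicate 2, 13 and 5 without OE7 replicate 1 and 2, 399 and 402 without OE5 replicate 1 and 2, and 268 with DESeq2 on recovered reads. Risen and fallen genes numbered 37 and 45 with pseudocount 0.1, 14 and 40 with no filter on low values, and 145 and 123 with DESeq2.

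**Figure D2:**
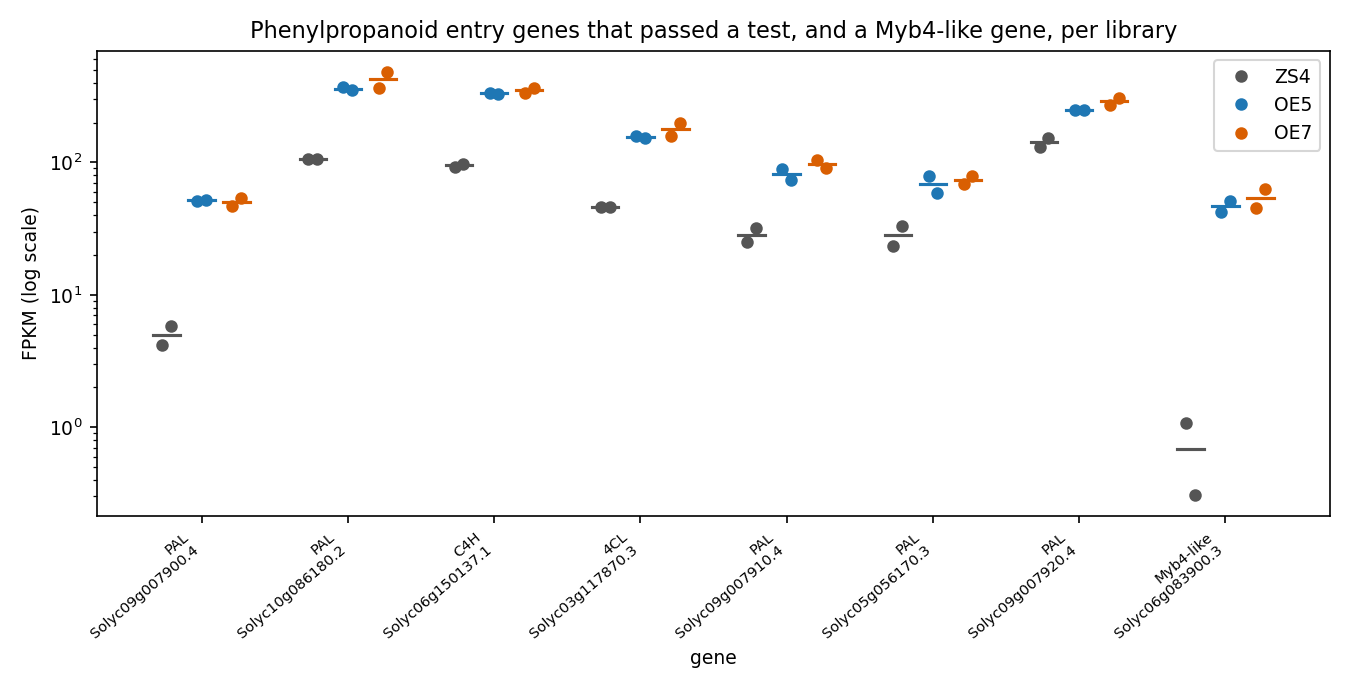
FPKM per library (y axis, log scale) of 7 phenylpropanoid entry genes and the Myb4-like gene (x axis) in ZS4 (grey), OE5 (blue) and OE7 (orange), with each point a library and each bar a mean of 2. In Solyc09g007900.4 the 4 overexpression libraries lie between 46.5 and 54.3 FPKM, against 4.19 and 5.81 in ZS4.

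The use of 2 independent lines asked which changes were common to both. Of the 78 and 105 genes called, 68 passed in both lines in the same direction, 30 risen and 38 fallen. Of these 68 genes, 28 were near 0 in every library of ZS4 or in every library of both lines. The causes of that pattern cannot be told apart here, as described below. Besides the phenylpropanoid and Myb4-like genes, a glutamic acid-rich protein-like gene (Solyc04g011550.2) rose from 15.2 ± 2.41 FPKM in ZS4 to 163 ± 9.43 in OE5 and 196 ± 6.75 in OE7 (SD, n = 2 each). A MADS AFFECTING FLOWERING 5-like gene (Solyc12g087830.2), of the MADS-box transcription factor family, rose from 4.48 ± 0.198 to 29.4 ± 0.438 and 33.95 ± 0.41 FPKM. A metallocarboxypeptidase inhibitor precursor gene (Solyc07g007250.4) rose from 0.685 ± 0.191 to 19.3 ± 10.6 and 32.7 ± 3.51 FPKM, and a cytochrome P450 98A2-like gene (Solyc01g096670.4), of the family that hydroxylates coumaroyl esters, from 10.6 ± 1.82 to 44.3 ± 2.73 and 44.5 ± 12.4 FPKM. The probable strigolactone esterase D14 homolog (Solyc05g018413.1), listed at 0 in both ZS4 libraries, was at 3.31 and 5.76 FPKM in OE5 and 4.43 and 8.45 in OE7.

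Several of the genes that fell in both lines were listed at 0 in every overexpression library. The histone H3.2-like gene Solyc01g073970.3 stood at 53.2 and 30.7 FPKM in the ZS4 libraries, or 220 and 127 reads, and at 0 in all 4 others. The glutaredoxin-C13-like gene (Solyc06g008760.1; 12.2 and 15.8 FPKM in ZS4), a pair of NRT1/PTR FAMILY 8.3-like transporter genes (Solyc12g042240.2, 10.6 and 5.69 FPKM, and Solyc12g042250.3, 6.98 and 5.63 FPKM) and SKP1-like protein 11 (Solyc11g008420.3; 15.1 and 6.35 FPKM) were also listed at 0 in all 4, and the calls of the last were lost in 10 of 16 alternatives for OE5 and 9 for OE7. An E3 ubiquitin-protein ligase COP1-like gene (Solyc11g011980.3) fell from 7.01 ± 1.40 FPKM to 0.280 ± 0.184 in OE5 and 0.185 ± 0.106 in OE7, and an adenosine kinase 2-like gene (Solyc09g007940.3) from 14.9 ± 3.79 to 0.170 ± 0.24 and 0.375 ± 0.191 FPKM (SD, n = 2 each). Histone H3 and NRT1/PTR genes have close copies (5 tested genes carry the histone H3.2-like description), so their single values are uncertain where reads map to several copies. Under all 16 alternatives that test single genes, the histone H3.2-like, Solyc04g011550.2 and Myb4-like genes remained called in both lines.

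With independent lists 0.0802 risen and 0.172 fallen genes would be shared, and 100 simulations of unchanged groups against the same ZS4 libraries shared 0.0600 genes on average and 2 at most. Summed over both lines, those simulations made 1.06 calls on average, against 183 observed, so they had few calls to share. They cannot show how much overlap the shared ZS4 libraries add among the observed calls. Across all 16602 genes, which are not independent replicates, the log2 fold changes of both lines correlated at Pearson's r = 0.642 and Spearman's rho = 0.431, against 0.499 and 0.473 in the simulations, and 58.8% had the same sign, against 66.7%. Their covariance was 0.102 against a simulated 0.0433, a difference of 0.0591, and against 0.0299 from the spread of the ZS4 libraries alone. The simulations gave all groups the same spread per gene, although ZS4 varied less than OE5 (root mean square SD 0.245 against 0.482). The simulated correlations and share of same signs are therefore no close baseline for the observed ones. With 1 ZS4 library for each line r was 0.479 or 0.298, and without OE5 replicate 1 or 2 it was 0.290 or 0.763. The controls cannot be split with 2 libraries on each side, so part of the overlap of calls beyond that of independent lists may come from the shared ZS4 libraries. Spearman's rho and the share with the same sign lay below their simulated values. Nothing is concluded from that, since the simulations gave ZS4 more spread than it had. The 68 shared calls became 9 and 44 without ZS4 replicate 1 and 2, 127 without OE5 replicate 1, 13 and 5 without OE7 replicate 1 and 2, 59 without OE5 replicate 2, and 146 with DESeq2 on recovered reads. Risen and fallen genes numbered 30 and 17 with pseudocount 0.1, 10 and 34 with no filter on low values, and 83 and 63 with DESeq2.

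**Figure D3:**
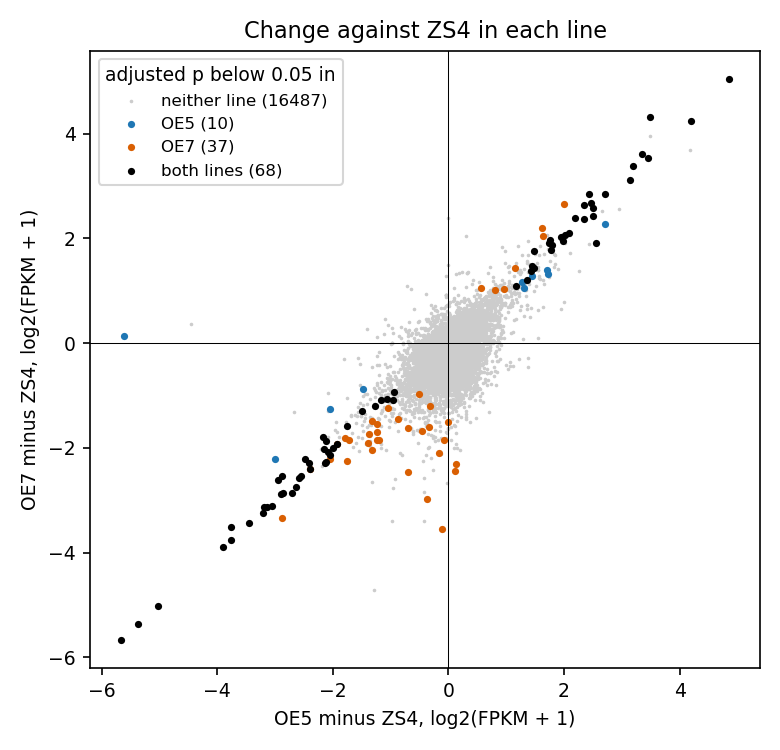
Log2 fold change of FPKM + 1 against ZS4 in OE5 (x axis) and OE7 (y axis) for the 16602 tested genes, coloured by the line or lines in which the adjusted p was below 0.05. The 68 genes that passed in both lines lie along the diagonal, and 10 and 37 passed in OE5 or OE7 alone.

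Taking the mean of both lines against ZS4, phenylpropanoid biosynthesis had the lowest adjusted p of the pathways tested for risen genes. Of the 141 genes that passed, 62 rose and 79 fell, and 8 of the 13 phenylpropanoid entry genes rose, or 9 adjusted over the list alone (camera adjusted p = 5.17e-22, adjusted p = 0.446 with an estimated correlation, fry adjusted p = 0.0218). Flavonoid 3',5'-methyltransferase (Solyc09g082660.3) and the crocetin glucosyltransferase-like gene were the 2 flavonoid and anthocyanin genes that rose, or 13 risen and 1 fallen adjusted over the list alone (camera adjusted p = 1.09e-10, adjusted p = 0.446 with an estimated correlation). Most alternatives ended these calls, 11 of 15 for the first and 10 of 15 for the second. The first stood at 86.2 ± 45.9, 287 ± 15.3 and 264 ± 6.06 FPKM in ZS4, OE5 and OE7 (SD, n = 2 each). A caffeic acid 3-O-methyltransferase-like gene (Solyc06g083450.4), of a lignin precursor enzyme, rose by a mean log2 fold change of 1.96 (limma adjusted p = 0.0217), the 1 risen member of 39 monolignol and lignin genes. Among genes with a pathway annotation, 12 of the 31 risen genes belonged to phenylpropanoid biosynthesis, against 0.729 by chance (one-sided Fisher's exact test, adjusted p = 2.25e-10). The 12 include the phenylalanine ammonia-lyase genes Solyc09g007900.4, Solyc09g007910.4 and Solyc09g007920.4, whose identifiers are close together. The test counts these as independent genes, and their single values are uncertain where reads map to several copies. Of the 32 fallen genes 7 belonged to plant-pathogen interaction, against 1.34 (one-sided Fisher's exact test, adjusted p = 0.0357). Among them Solyc01g005720.3, Solyc01g005730.3 and Solyc01g005760.3 have identifiers close together, and the test counts them as independent genes.

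Pathogenesis-related genes had 2 members fallen, or 4 adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.897 with an estimated correlation). Heat shock genes had 1 fallen, or 6 adjusted over the list alone (camera adjusted p = 0.00676, adjusted p = 0.897 with an estimated correlation), and ribosomal protein genes were higher with 0 past the limma test and 0 adjusted over the list alone (camera adjusted p = 2.85e-04, adjusted p = 0.897 with an estimated correlation). The other lists did not pass for the mean of both lines. Camera adjusted p was 0.386 for monolignol and lignin genes, 0.0520 for the known flavonoid regulators, 0.386 for MYB, 0.321 for antioxidant enzymes, 0.0849 for class III peroxidases, 0.745 for glutathione transferases, 0.210 for UDP-glycosyltransferases and 0.386 for cytochrome P450 genes. It was 0.386 for ABC and MATE transporters, 0.853 for jasmonate, 0.484 for ethylene, 0.991 for ABA and water deficit, 0.777 for photosynthesis, 0.386 for cell wall, 0.172 for cell cycle and histone genes, 0.0692 for WRKY and 0.386 for a list of aldo-keto and quinone reductases, 12-oxophytodienoate reductases and aldehyde dehydrogenases. Adjusted over the list alone, 1 monolignol gene, 2 MYB genes and 2 genes of the reductase and dehydrogenase list rose, 4 WRKY genes, 1 class III peroxidase, 1 ethylene gene and 1 histone gene fell. The 1 member of the reductase and dehydrogenase list that also rose over all genes was aldehyde dehydrogenase family 2 member C4 (Solyc12g007030.3; mean log2 fold change 1.06, limma adjusted p = 0.0495), which is annotated to phenylpropanoid biosynthesis. Likewise 3 glutathione transferases rose and 1 fell, 4 UDP-glycosyltransferases rose and 2 fell, 2 cytochrome P450 genes rose and 2 fell, and 1 photosynthesis gene rose and 2 fell. Markers of other tissues or harvest time gave 0.210 for glandular trichome, 0.736 for root and 0.416 for circadian clock genes. In OE7 alone all 7 trichome genes were lower (median log2 fold change −0.70, camera adjusted p = 0.0519, adjusted p = 0.761 with an estimated correlation). Of 9 root genes 8 were lower in OE7, with 2 fallen adjusted over the list alone (camera adjusted p = 0.511), and of 20 clock genes 15 (camera adjusted p = 0.948). Without 1 library, the ribosomal list turned (OE5 replicate 2, camera adjusted p = 0.0988) or ended (OE7 replicate 1, 0.166), and the pathogenesis-related (OE7 replicate 1, 0.0634) and heat shock (OE5 replicate 1, 0.0578) calls ended. The 141 calls became 21 and 61 without ZS4 replicate 1 and 2, 224 and 424 without OE5 replicate 1 and 2, 31 and 35 without OE7 replicate 1 and 2, and 289 with DESeq2 on recovered reads. Risen and fallen genes numbered 62 and 52 with pseudocount 0.1, 30 and 68 with no filter on low values, 67 and 121 with edgeR, and 158 and 131 with DESeq2.

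Compared directly, OE7 and OE5 differed in 3 genes. The salicylic acid carboxyl methyltransferase gene Solyc09g091550.3 was lower in OE7, at 1.61 ± 0.24 FPKM against 14.9 ± 2.67 in OE5 (SD, n = 2 each; limma log2 fold change −2.60 ± 0.23 SE, adjusted p = 0.0266). A gene described as chloroplast NADH-plastoquinone oxidoreductase subunit 7 (Solyc00g500087.1) was listed at 12.1 and 7.91 FPKM in OE5 and at 0 in both OE7 libraries (limma adjusted p = 0.0189), a call lost in 11 of 16 alternatives. That description is carried by 3 tested genes, so its single values are uncertain where reads map to several copies. An uncharacterized gene (Solyc03g059170.2; chosen after its values were seen) was listed at 57.0 and 40.7 FPKM in ZS4, 79.1 and 35.2 in OE7 and 0 in both OE5 libraries (limma adjusted p = 0.00521). At an unadjusted p below 0.05 there were 692 genes. The 3 calls became 1 without either ZS4 or either OE7 library and 2888 without OE5 replicate 1. They became 17 with DESeq2 on recovered reads, and 0 by limma with no filter on low values, where edgeR with no filter called 4. Of 74 photosynthesis genes 71 were higher in OE7 than in OE5 (camera adjusted p = 1.99e-34, adjusted p = 0.850 with an estimated correlation), with 0 past the limma test, also when adjusted over the list alone. The median log2 deviation of photosynthesis genes in OE5 replicate 2, the library that stood apart, was −0.27, against 0.02 in random lists of like abundance, and without that library the camera adjusted p was 5.80e-08. Of 76 cell cycle and histone genes 68 were lower in OE7 than in OE5 (camera adjusted p = 0.00460, adjusted p = 0.874 with an estimated correlation), with 0 past the limma test, also when adjusted over the list alone. Without OE5 replicate 2 the cell cycle list turned direction (0.0749), and without OE7 replicate 2 its call ended (0.153).

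In the authors' deposited tables, fewer genes were marked for OE5 than for OE7. The authors' deposited table marked 30 genes as up and 39 as down in OE5, and 81 up and 119 down in OE7. The smallest absolute log2 fold change among the marked genes in the authors' deposited table was 1.00 in either line. Of the 78 OE5 and 105 OE7 genes that passed here, 44 and 81 were marked in the authors' deposited table. Marked or not, 125 and 531 genes had an adjusted p below 0.05 in the authors' deposited table. Of the 78 and 105 genes, 63 and 94 were among these, and all of the 63 and 94 had the same direction there.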

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

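Tests of chromosome segments, the shift by overexpression, depth, physiological state and multiplied size factors were chosen after the results were seen; those of near-identical copies, a wrong label and gene length were planned before.

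The difference between the lines was tested directly, and 3 genes and 10 gene lists passed. Solyc03g059170.2, uncharacterized, was higher in OE7 and listed at 0 in OE5 (limma adjusted p = 0.00521). The salicylic acid carboxyl methyltransferase gene Solyc09g091550.3 (limma adjusted p = 0.0266) was lower in OE7. So was Solyc00g500087.1, described as a chloroplast NADH-plastoquinone oxidoreductase subunit (limma adjusted p = 0.0189). Photosynthesis genes were higher in OE7 than in OE5 in 71 of 74 cases (camera adjusted p = 1.99e-34). Relative to all genes, whose median log2 difference was −0.18, phenylpropanoid entry (camera adjusted p = 0.0233), MYB (0.00315), UDP-glycosyltransferase (0.0375), cytochrome P450 (0.0361), ethylene (0.0375) and ABA and water deficit genes (0.0361) were also higher. Pathogenesis-related (camera adjusted p = 0.00460), class III peroxidase (0.0361) and cell cycle and histone genes (0.00460) were lower. With an estimated correlation each list had an adjusted p between 0.850 and 0.874. All but the photosynthesis and pathogenesis-related calls were lost without OE5 replicate 2, and the pathogenesis-related call was lost without OE5 replicate 1 (camera adjusted p = 0.0799).

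The first pattern is a set of 34 genes near 0 in every library of ZS4 or in every library of both lines, 23 of them near 0 in the lines and 11 near 0 in ZS4, and 28 of the 34 passed in both lines. ZS4 against OE5 gave 40 such genes, ZS4 against OE7 53 and OE5 against OE7, which share the transgene, 11. Overexpression may turn such genes on or off, but so may chromosome segments that differ between ZS4 and the plants that were transformed, or reads moved between near-identical copies, and these cannot be told apart here. In the order of the identifiers, which placed 31 of the 34 genes, 1 pair lay within 2 tested genes of each other (permutation p = 0.104), both NRT1/PTR FAMILY 8.3-like, while at wider steps, chosen after the identifiers were seen, 4 pairs lay within 20 and 11 within 50 genes, against medians of 1 and 3 in 10000 random sets (permutation p = 0.0199 and 0.0001, the latter the smallest they can give), so segments stay open. Only 50% of the genes had a description to match with other copies, which is too few for that test, although 0 of the 17 described had a gene of the same description that changed the other way in both lines.

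The second pattern is OE5 replicate 2, which differed from its partner more than any other pair of replicates. A ZS4 library under the wrong label is argued against, since 96.6% of the 59 genes called in both lines without it lay nearer to the other 3 overexpression libraries, and so is lower depth, since its reads differed by −0.801% from the mean of the others. The deviation of each gene correlated with its length at Spearman's rho = 0.124 across genes, which leaves a part for gene length open. Photosynthesis genes were lower in it than in random lists of like abundance (median −0.27 against 0.02, permutation p = 0.0002, two-sided, the smallest that 10000 random lists can give), while cell cycle and histone genes (0.99) and ribosomal protein genes (0.69) were higher. UDP-glycosyltransferase (0.07 against 0.31), cytochrome P450 (0.01 against 0.30) and ABA and water deficit genes (0.09 against 0.30) were also lower, at the same permutation p. Clock genes were lower too (−0.04 against 0.26, permutation p = 0.002), so photosynthesis is not singled out. The random lists were drawn gene by gene and ignore correlation within a list. Another physiological state or another hour of harvest may account for these shifts, as a hypothesis found and tested on the same data.

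The third pattern is in the authors' deposited table, where group means and fold changes differ in sign for 18.4% of 11884 genes in OE5 and 43.4% of 11057 genes in OE7 with a mean above 50, and for 0 of those with an adjusted p below 0.05. The factors read from the deposited means lay within 0.0649% of DESeq2 size factors of the recovered reads, and up to 37.7% from their reciprocals. A candidate explanation is that reads were multiplied by the size factors, where division is usual, in the means alone. The log2 fold changes in the authors' deposited table correlated with those of a DESeq2 repeat with shrinkage on the recovered reads at r = 0.9995 in OE5 and 0.9998 in OE7 across genes. No biological explanation was tested for this pattern.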

How the results depend on the processing

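The tests on recovered reads, the scaling to equal medians, the list tests with pseudocount 0.1 and the fold change correlation without 1 OE5 library were chosen after seeing the data. In the counts of this section, the genes named by the rule include Solyc03g059170.2, which was chosen after its values were seen and was called in OE5. None of the genes named by the rule and called, 36 in OE5 and 43 in OE7, changed direction under any alternative, while 20 of 113 in OE5 and 15 of 106 in OE7 named but not called did. The other genes chosen after their values were seen and those added for the mean or for OE7 against OE5 kept their direction too, but each lost its call under 2 or more of 15 or 16 alternatives. The OE5 call of Solyc03g059170.2 was lost in 0 of 16, and its call for OE7 against OE5 in 3 of 16. Most alternatives ended the call of 12 of the 36 and 4 of the 43 genes named by the rule, and of 3 of 6 (OE5), 2 of 7 (OE7), 2 of 3 (mean) and 1 of 3 (OE7 against OE5) of the others. Total counts within 1.5 times of those reported came with pseudocount 0.1, equal medians, an absolute log2 fold change of at least 1, and edgeR without a block. The split moved more, with fallen genes at 23 in OE5, 45 in OE7, 17 in both lines and 52 in the mean with pseudocount 0.1, against 42, 68, 38 and 79, and at 121 in the mean with edgeR. Called genes for OE5, OE7, both lines, OE7 against OE5 and the mean were 182, 268, 146, 17 and 289 with DESeq2, and 29, 32, 26, 1 and 63 with the replicate block. No filter on low values gave 49, 54, 44 and 0 (limma; edgeR with no filter called 4) for the first 4, and edgeR with a replicate block 33, 63 and 29 for the first 3. Only the 4 libraries compared gave 24 for OE5, 409 for OE7 and 1 for OE7 against OE5. Deviations of same-numbered replicates correlated at −0.323 (ZS4 and OE5), 0.035 (ZS4 and OE7) and −0.051 (OE5 and OE7), so replicates of the same number did not move together. OE5 replicate 2 correlated at 0.961 with ZS4 replicate 1 and at 0.953 with ZS4 replicate 2, and OE5 replicate 1 at 0.962 and 0.973. A batch that crosses the replicate numbers is therefore not excluded. Leaving out 1 library gave 10 to 302 (OE5), 5 to 402 (OE7), 5 to 127 (both), 1 to 2888 (OE7 against OE5) and 21 to 424 genes (mean). The wide OE5 replicates set the shared spread, so leaving either out raises the OE7 count by construction; the cause of the other changes was not tested. Called lists went from 6, 10, 5 and 10 (OE5, OE7, mean, OE7 against OE5) to 0 each with an estimated correlation and to 1, 1, 1 and 0 with fry, and without 1 library to 6 to 11, 8 to 14, 3 to 11 and 6 to 12. The fold change correlation was 0.479 and 0.298 with 1 ZS4 library per line and 0.290 to 0.763 without 1 OE5 library; the filter at 1 FPKM is the one already used. Directions turned, with these adjusted p, without OE5 replicate 2 for photosynthesis (0.817, otherwise down to 5.26e-27) and ribosomal genes (1.09e-07, range without 1 library 2.41e-29 to 0.00801) in OE5, ribosomal genes in the mean (0.0988, range 7.03e-29 to 0.166), and UDP-glycosyltransferases (0.548, lowest 7.00e-04), cytochrome P450 (0.427, lowest 3.14e-04) and cell cycle genes (0.0749, range 6.17e-10 to 0.153) in OE7 against OE5. They turned without OE7 replicate 1 for ribosomal genes in OE7 (0.752, lowest 3.34e-08), and with fry for UDP-glycosyltransferases (0.733) and ribosomal genes (0.975) in OE7 and for MYB (0.946), UDP-glycosyltransferases (0.576), cytochrome P450 (0.627), ethylene (0.677) and ABA genes (0.677) in OE7 against OE5. Fry tests movement from 0 and camera against other genes, which differ where all genes shift. The list called with fry in OE5, OE7 and the mean was phenylpropanoid entry (fry adjusted p = 0.0367, 0.0320 and 0.0218). Of the genes named by the rule and called, 7 in OE5 and 3 in OE7 were still called in the least favourable setting, without ZS4 replicate 1 and without OE7 replicate 2. The replicate block ended 1 list call, class III peroxidases in OE7 against OE5 (0.0573), and ended no other. At this depth genes with a mean under 1 FPKM were not tested.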

Other observations

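The pathway tests below were chosen after seeing the data.

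The genes of ornithine decarboxylase and S-adenosylmethionine decarboxylase rose in both lines. That of ornithine decarboxylase (Solyc04g082030.1), which makes putrescine, stood at 20.47 and 22.9 FPKM in the ZS4 libraries and at 51.3 to 74.7 FPKM in the 4 overexpression libraries (limma log2 fold change 1.45 in OE5 and 1.47 in OE7, adjusted p = 0.0355 and 0.0309). That of S-adenosylmethionine decarboxylase (Solyc05g010420.2), which supplies the aminopropyl group of spermidine and spermine, stood at 533 and 555 FPKM in ZS4 and at 1029 to 1298 FPKM in the lines (1.16 and 1.09, limma adjusted p = 0.0281 and 0.0327). With Solyc05g010425.1, described as a hypothetical protein, they made 3 of the 16 annotated genes that rose in both lines part of arginine and proline metabolism, against 0.194 by chance (one-sided Fisher's exact test, adjusted p = 0.0271). For the mean of both lines this pathway had an adjusted p = 0.127 by the same test. Solyc05g010420.2 and Solyc05g010425.1 have neighbouring identifiers, and the test counts them as independent genes, so it may overstate a change of the pathway. These genes were chosen after their values were seen, and under 16 alternatives the call of ornithine decarboxylase was lost in 12 for OE5 and 7 for OE7, that of S-adenosylmethionine decarboxylase in 12 and 11, and that of Solyc05g010425.1 in 13 and 11.

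A pair of receptor-like protein 12 genes annotated to plant-pathogen interaction fell in both lines. They stood at 3.27 and 4.17 FPKM (Solyc01g005720.3) and 5.96 and 4.57 FPKM (Solyc01g005760.3) in ZS4, and at 0 to 0.280 and 0.120 to 0.370 FPKM in the overexpression libraries (limma adjusted p = 0.0328 and 0.0134 in OE5, 0.0341 and 0.01998 in OE7). A gene described as NL0C (Solyc01g005730.3) stood at 7.96 and 8.36 FPKM in ZS4, was listed at 0 in 3 overexpression libraries and had 0.0800 FPKM in OE7 replicate 2. The receptor-like protein 12 genes were chosen after their values were seen. For fallen genes the plant-pathogen interaction pathway had an adjusted p = 0.0145 in OE7, 0.0357 for the mean of both lines, 0.143 in OE5 and 0.0985 for genes that fell in both lines (one-sided Fisher's exact test). The receptor-like protein 12 genes and the NL0C gene are all annotated to this pathway and have identifiers close together. The test counts them as independent genes, so its p-values may overstate a change of the pathway.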
